A study of Mus musculus with 8 samples.

How the data were processed

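Gene expression was measured by microarray in dermal fibroblasts of 8 mice, 4 treated with GW9662 and 4 with vehicle, with 1 array per animal. Per the labels, GW9662 at 150 nmol in 300 µl acetone, or acetone alone, was put on the back skin 3 times a week for 6 months, from 12 months of age. Fibroblasts were sorted as Pdgfra-positive and Cd34-positive cells that lacked CD45, CD117, CD24, CD31 and EpCam. Per the labels' protocols, RNA came from 5000 sorted cells, was amplified over 21 cycles, and 7.8 µg of cDNA was labelled and hybridised to a perfect-match mouse array. Amplification from few cells can change the relative signal of transcripts and of their 3' and 5' ends.

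The deposited values are log2 signal intensities given to 2 decimals for 45141 probe sets in each of the 8 samples. The submitters' processing notes name RMA and the affy package, without versions. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a set. The base of the logarithm is not given in the sources used here and was read from the range of the values. The sample medians lay between 4.63 and 4.69, so no further scaling was applied in the main test. No detection calls were part of the values used, so whether a probe set was above background is not known, and levels of different probe sets were not compared as amounts of transcript; they were ranked only to choose a gene's probe set, to set apart the brighter genes, and to pick the brightest genes of a list. For arrays, the number of animals limits the precision. All value columns were mapped to a sample.

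Probe sets were named through the platform annotation and a mouse gene table. Of the probe sets, 28898 had 1 gene, 551 had several and were left out, and 15692 were unnamed here, among them 104 control probe sets. For 209 named probe sets without a match in the gene table, the annotation's own symbol was kept. Of the genes, 7180 had more than 1 probe set, and the set with the highest mean over the 8 samples stood for the gene. This left 17097 genes.

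The comparison was GW9662 minus vehicle, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, no filter on dim genes) with Benjamini-Hochberg adjustment over all 17097 genes and a threshold of 0.05. Tests were two-sided. A total of 27 gene lists, 7 of them markers of other cell types in skin, was written before the data were examined, and 788 of their 877 distinct genes were measured. Lists were compared with all other genes by limma's camera with its preset correlation of 0.01, adjusted over the 27 lists. The mean shift of the adipocyte and PPARG target list was also tested by an exact permutation of the 70 assignments of 8 samples to groups, for which the smallest possible p is 0.0286. The same test was run beside it on the means of the other lists. It does not use the pairs of samples described below, and neither do the SEs of the list means. An exact permutation test that flips the signs of the 4 pair differences was also run on the list means. Its smallest possible p is 0.125. The named genes were fixed by a rule: Pparg and the genes of the sort markers, up to 10 genes per direction past the threshold or, where fewer passed, the genes of smallest unadjusted p whose groups did not overlap, and the 3 members of smallest unadjusted p in each list. Predicted genes and genes without an ordinary symbol were passed over. This gave 107 genes.

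The description of the design says that 1 animal of each group was taken on the same day. Deviations from the group means correlated between same-numbered samples at 0.203, 0.163, 0.114 and 0.165 for numbers 1 to 4, across genes, and each of the 8 samples correlated best with the sample of its own number in the other group. The numbers were therefore read as pairs. The main test does not use the pairs, and a fit with the replicate number as a block was run beside it. No pair of samples shared more than 3.05% of its values, and correlations between samples over genes ranged from 0.990 to 0.997, so all 8 were counted as separate.

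Alternatives were the block, eBayes with a trend and robust variances, the brighter genes alone, the mean of a gene's probe sets, renewed quantile normalisation, centring on sample medians, array weights, each sample left out, all probe sets, other thresholds, and for lists camera with an estimated correlation and fry. After the values had been seen, a fit without vehicle 4 and GW9662 3, fits without vehicle 4 and GW9662 4 with and without the block, and camera with an estimated correlation together with the block, were added.

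The procedure was tested on simulated data made from the spread of these 17097 genes, with 200 genes changed. The limma test recovered 84.0% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2. Genes and samples varied independently there, without pairs or an outlying sample. These shares therefore do not bound what the test can find in the real samples. In 50 simulations of the ribosomal protein list in this comparison, camera with the preset correlation called a shift of 0.1 in 100% where genes varied independently. It also called an unchanged list in 38.0% where the genes were correlated at 0.5, against 0% with an estimated correlation. The correlation later estimated for this list was higher, 0.658. A shifted list of correlated genes was not simulated, so how often the estimated correlation misses a shift is not known. Plots were drawn with matplotlib 3.10.9.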

Results

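The data comprised expression profiles of Pdgfra-positive, Cd34-positive dermal fibroblasts from the back skin of 8 mice aged 12 months at the start of 6 months of topical treatment. GW9662, an irreversible antagonist of the nuclear receptor PPARG, was applied in acetone to 4 animals, and acetone alone to the other 4. PPARG drives adipocyte differentiation and lipid storage. The question addressed by the comparison was how long-term PPARG inhibition alters gene expression in dermal fibroblasts of ageing skin.

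No single gene passed the test between fibroblasts of GW9662-treated and vehicle-treated skin. The lists of collagens and of matrix processing genes were higher after GW9662, by means of 0.12 and 0.09 on the log2 scale, and the list of ribosomal proteins was lower, with a mean of -0.11. These 3 calls were made with genes taken as nearly independent. None held with an estimated correlation (camera unadjusted p = 0.2615, 0.1189 and 0.2183 in the same order, adjusted p = 0.981 for each). Nearly all of the 27 lists share that adjusted value. The exact permutation p of the 3 list means was 0.314, 0.229 and 0.171 without use of the pairs. The exact permutation test that flips the signs of pair differences gave p = 0.25, 0.125 and 0.125. The smallest p it can give is 0.125, so it cannot reach the threshold. PPARG target genes of adipocytes had a mean shift of -0.0054 ± 0.039 (SE, n = 4 per group). Of the 17097 genes, 0 had an adjusted p under 0.05 in limma (smallest adjusted p = 0.997). At an unadjusted p under 0.05 there were 578 genes, 268 higher and 310 lower, where chance gives 854.8 if samples are independent. Same-numbered samples were correlated, so that figure need not hold here. Other groupings of the samples that part all 4 pairs gave 353 to 820 genes (median 700). With the replicate block there were 825 genes. An absolute log2 fold change over 0.5 was found in 26 genes, 23 higher and 3 lower, and over 1 in 0 genes. The largest was 0.98. The groups did not overlap in 300 genes, or 1.76%, where chance gives 2.86% if samples are independent.

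Pparg itself, the gene of the inhibited receptor, measured 4.85 ± 0.27 (SD, n = 4) after GW9662 and 4.88 ± 0.23 in vehicle, a log2 fold change of -0.02 with a 95% interval from -0.34 to 0.30. Of the genes of the positive sort markers, Cd34 measured 10.72 ± 0.04 and 10.72 ± 0.15 (SD, n = 4 each). Pdgfra, a growth factor receptor of fibroblasts, had a log2 fold change of 0.10 ± 0.12 (SE). Among the genes of the markers sorted against, the log2 fold change was -0.0025 ± 0.06 for Ptprc (CD45), 0.05 ± 0.06 for Kit (CD117), -0.02 ± 0.08 for Cd24a, 0.12 ± 0.14 for Pecam1 (CD31) and 0.14 ± 0.07 for Epcam (SE). All 8 had an adjusted p of at least 0.997 in limma, and the sign of Pparg, Pdgfra, Ptprc and Cd24a turned in some of the alternatives.

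**Figure D1:**
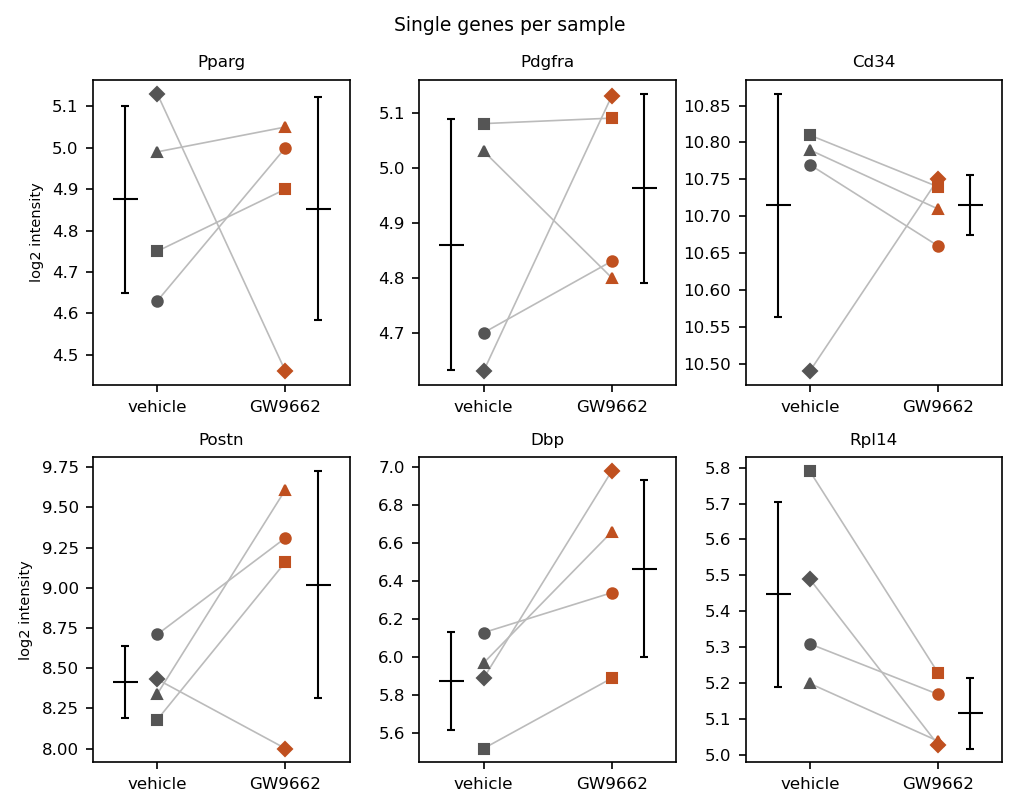
Log2 intensity (y axis) of 6 genes in the 4 vehicle and 4 GW9662 samples (x axis), with circles, squares, triangles and diamonds for replicates 1, 2, 3 and 4, grey lines joining equal numbers, and black marks for the mean and SD. Dbp was higher in GW9662 in 4 of 4 pairs and Rpl14 lower in 4 of 4, and the groups overlap in each panel.

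Among genes whose groups did not overlap, the 10 of smallest unadjusted p on each side are given as values, since none passed adjustment. On the higher side, Spred1, an inhibitor of Ras to MAP kinase signalling, stood at 7.75 ± 0.04 against 7.38 ± 0.10 (SD, n = 4), a log2 fold change of 0.37 ± 0.07 (SE). L3hypdh, Nadk2, the mitochondrial NAD kinase, Ap1ar, Pter, Myo5a, Usp32, Pdcl, Ktn1 and Cryzl2 followed with log2 fold changes from 0.22 to 0.40. On the lower side, Mc1r, the melanocortin receptor known from pigment cells, stood at 4.70 ± 0.05 against 5.06 ± 0.13, a log2 fold change of -0.37 ± 0.07. Gtf2f2, a subunit of general transcription factor TFIIF, Twf2, Tafa5, Hmgb2, Iglv1, Tbrg4, Ccdc159, Card6 and Map3k14, the NF-kappa-B-inducing kinase, followed with log2 fold changes from -0.40 to -0.21. Limma's adjusted p was 0.997 for each of these 20 genes. With the mean of all probe sets of a gene in place of 1 set, 10 of the 20 values were over 1.5 times smaller, among them Nadk2 (0.10), Ap1ar (0.11), Ktn1 (0.09), Myo5a (0.13) and Mc1r (-0.16).

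Lipid genes, many of them known targets of PPARG, showed no shift past the main test. Of 33 measured genes of the adipocyte and PPARG target list (41 fixed), 12 were higher and 21 lower by any amount, with a median log2 fold change of -0.015. In limma 0 passed over all genes, 0 adjusted over the list alone, and 0 at an unadjusted p under 0.05. The list mean was 0.0027 below the overall mean in GW9662 and 0.0027 above it in vehicle, with SDs of 0.032 and 0.072 (n = 4 each) and an exact permutation p of 0.943. It was higher in 2 pairs and lower in 2. The members of smallest p were Klf15, a regulator of adipogenesis, at -0.19 ± 0.09 (SE), Dgat2, which makes triglycerides, at 0.15 ± 0.09, and Adipoq, the adiponectin gene, at -0.09 ± 0.07. In the list of fatty acid and triglyceride synthesis, 14 of 26 measured genes were higher and 12 lower (median 0.02, camera adjusted p = 0.942), with Fads2, a desaturase, at -0.15, Gpat4 at 0.12 and Acsl4 at -0.20 (0.08 with the mean of its probe sets, -0.05 without vehicle 1). Cholesterol synthesis had 14 of 19 measured genes lower (median -0.07, camera adjusted p = 0.283), among them Tm7sf2 at -0.18, Hmgcs1 at -0.13 and Msmo1 at -0.08 (0.04 with the mean of its probe sets). With the preset correlation this list was called lower without GW9662 1 (adjusted p = 0.00643), without vehicle 4 (0.00823), and without both vehicle 4 and GW9662 3 (0.0476), and on all 8 samples it had an adjusted p of 0.981 with an estimated correlation. Fatty acid oxidation had 15 of 23 lower (median -0.02, camera adjusted p = 0.896), among them Eci1 at -0.15, Echs1 at -0.16 and Cpt2 at -0.12. In these 3 lists too, 0 genes had an unadjusted p under 0.05 in limma.

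Genes of the extracellular matrix were on balance higher after GW9662. In the list of collagens and fibrillar matrix, 26 of 41 measured genes were higher and 15 lower, with a mean log2 fold change of 0.12 ± 0.10 (SE) and a median of 0.08 (camera adjusted p = 0.0112 with the preset correlation; adjusted p = 0.981 with an estimated correlation). Postn, periostin, a matrix protein of remodelling tissue, was at 0.61 ± 0.29 (SE). It was at 0.41 without GW9662 3 and at up to 0.945 with another sample left out. Col14a1 was at 0.70 ± 0.36 (0.43 without GW9662 1, 1.08 without vehicle 4 and GW9662 4). Col5a2, a chain of type V collagen, was at 0.31 ± 0.15 (0.23 without GW9662 3, up to 0.47 with another sample left out). The list mean was higher in 3 of 4 pairs. In the list of matrix processing and remodelling, 29 of 38 measured genes were higher and 8 lower, with a mean of 0.09 ± 0.07 and a median of 0.08 (camera adjusted p = 4.84e-04; adjusted p = 0.981 with an estimated correlation). The list mean was higher in 4 of 4 pairs, though in pair 3 by only 0.0187. Ctsk, the collagen-degrading protease cathepsin K, was at 0.27 ± 0.11, Plod1, a lysyl hydroxylase of collagen, at 0.26 ± 0.13 (0.14 without vehicle 4 and 0.14 with the mean of its probe sets) and Adamts12 at 0.32 ± 0.16 (0.21 without GW9662 1). In the main test no member passed limma over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 0 of the 41 and 1 of the 38, Ctsk. Vehicle 4, which lay apart from the other 7 samples on the first principal component (22.2 against -10.4 to 5.49), had the lowest mean of its group in both lists, and so had its partner GW9662 4. Without vehicle 4 the means were 0.09 and 0.05 and the adjusted p 0.292 and 0.0476 with the preset correlation. The collagen call also ended without GW9662 1 (0.0818, mean 0.11), GW9662 2 (0.0742, mean 0.11) or GW9662 3 (0.258, mean 0.06) and among the brighter genes alone (0.155, mean 0.09), while without GW9662 4 the means were 0.22 and 0.14. Without both vehicle 4 and GW9662 3, a choice made after seeing the data, the adjusted p was 0.867 for collagens and 0.0825 for matrix processing. Without the pair of vehicle 4 and GW9662 4, likewise chosen after seeing the data, the means were 0.19 ± 0.05 and 0.10 ± 0.05 (SE, n = 3 per group). With the block on these 3 pairs Col14a1 passed limma's test over all genes (adjusted p = 0.0396), as no gene did in any other fit.

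**Figure D2:**
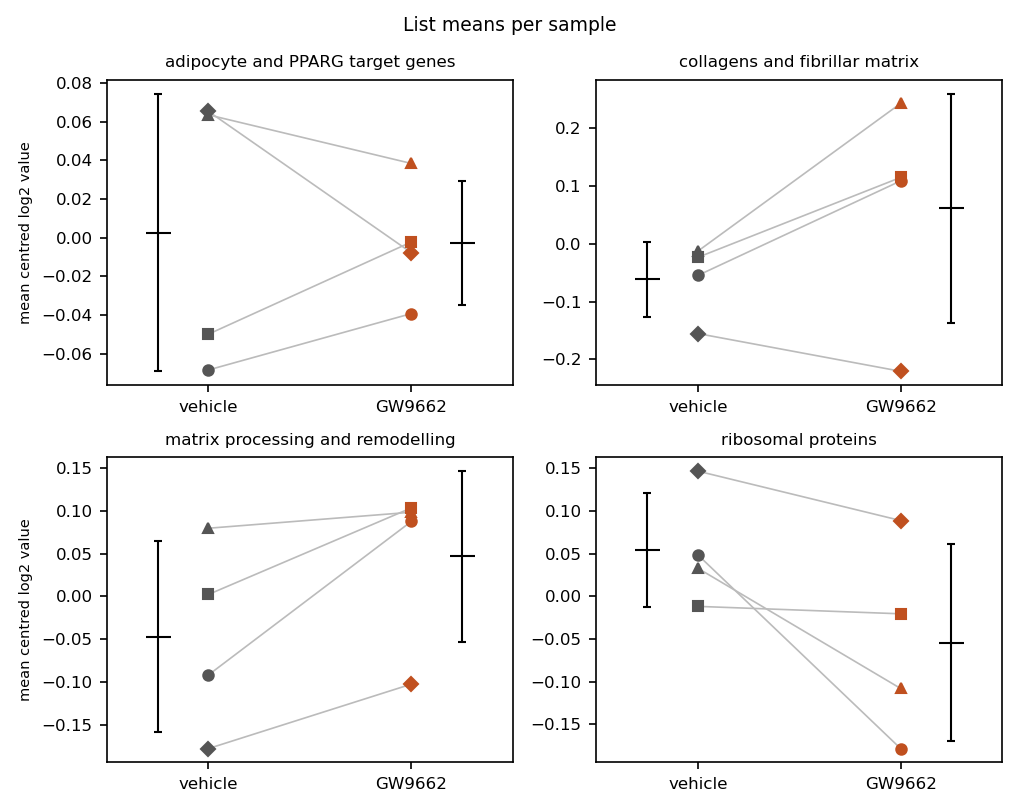
Mean over list genes of log2 values centred per gene (y axis) for 4 lists in the 4 vehicle and 4 GW9662 samples (x axis), with circles, squares, triangles and diamonds for replicates 1, 2, 3 and 4, grey lines joining equal numbers, and black marks for the mean and SD. Ribosomal proteins lie lower in GW9662 in 4 of 4 pairs (pair 2 at only -0.0087). Matrix processing genes lie higher in 4 of 4 (pair 3 at only 0.0187). The SDs of the groups overlap in each panel.

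Ribosomal protein genes had lower values after GW9662 in nearly all members, by a small amount, though the animals of the groups overlapped. Of 47 measured genes, 46 were lower and 1 was higher, with a median log2 fold change of -0.09 and a mean of -0.11 ± 0.07 (SE). The camera adjusted p was 5.74e-09 with the preset correlation and 0.981 with an estimated correlation. That estimate was 0.658, so the genes moved largely together and add little to the number of animals. The exact permutation p of the list mean was 0.171. The mean was lower in 4 of 4 pairs, in pair 2 at only -0.0087. The exact permutation test that flips the signs of pair differences gave p = 0.125, and with 4 pairs it cannot give a smaller one. Rpl14, at -0.33 ± 0.12 (SE; -0.22 without vehicle 2), was the 1 member with an unadjusted p under 0.05. Rps10 was at -0.23 ± 0.11 and Rps24 at -0.20 ± 0.10. In all, 0 genes passed limma's test over all genes or adjusted over the list alone. Without GW9662 1 the mean was -0.07 (adjusted p = 5.43e-04 with the preset correlation), and without vehicle 4, the highest of its group, it was -0.08 (1.74e-04). Oxidative phosphorylation had 28 of 44 measured genes lower (median -0.02, camera adjusted p = 0.456), with Ndufs8 at -0.37 (-0.19 without GW9662 4), Ndufb5 at -0.13 and Cycs, cytochrome c, at -0.16. With the preset correlation it was called lower with array weights (adjusted p = 0.0478), without GW9662 2 (0.00127), without vehicle 4 (1.74e-04), without vehicle 4 and GW9662 3 (0.0153), and without vehicle 4 and GW9662 4 (0.00117). On all 8 samples it had an adjusted p of 0.981 with an estimated correlation.

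Clock genes gave the highest median of the 27 lists. In the circadian clock list, 15 of 21 measured genes were higher and 6 lower, with a median of 0.09 and a mean of 0.08 ± 0.09 (SE; camera adjusted p = 0.0516, and 0.981 with an estimated correlation). Dbp, a transcription factor driven directly by the clock, was at 0.59 ± 0.21 (SE), Cry2, a repressor of the clock, at 0.29 ± 0.12 and Hlf at 0.19 ± 0.10. Both Dbp and Cry2 were higher in 4 of 4 pairs, while the list mean was higher in 2 pairs and lower in 2. They were the 2 members with an unadjusted p under 0.05 in limma, and 0 passed adjusted over the list alone. The adjusted p lay under the threshold with the mean of all probe sets of a gene (0.0110), with trend and robust variances (0.0461), and without GW9662 1 (0.0069), GW9662 2 (1.56e-04), vehicle 1 (0.0241) or vehicle 3 (0.0222). It was 0.707 without GW9662 4, with a mean of 0.02, 0.370 without vehicle 2, 0.271 without GW9662 3, 0.191 without vehicle 4, 0.534 without both vehicle 4 and GW9662 3, 0.867 without both vehicle 4 and GW9662 4 (mean 0.0035), 0.163 among the brighter genes, 0.121 with array weights and 0.0730 to 0.0863 with the block or another scaling.

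**Figure D3:**
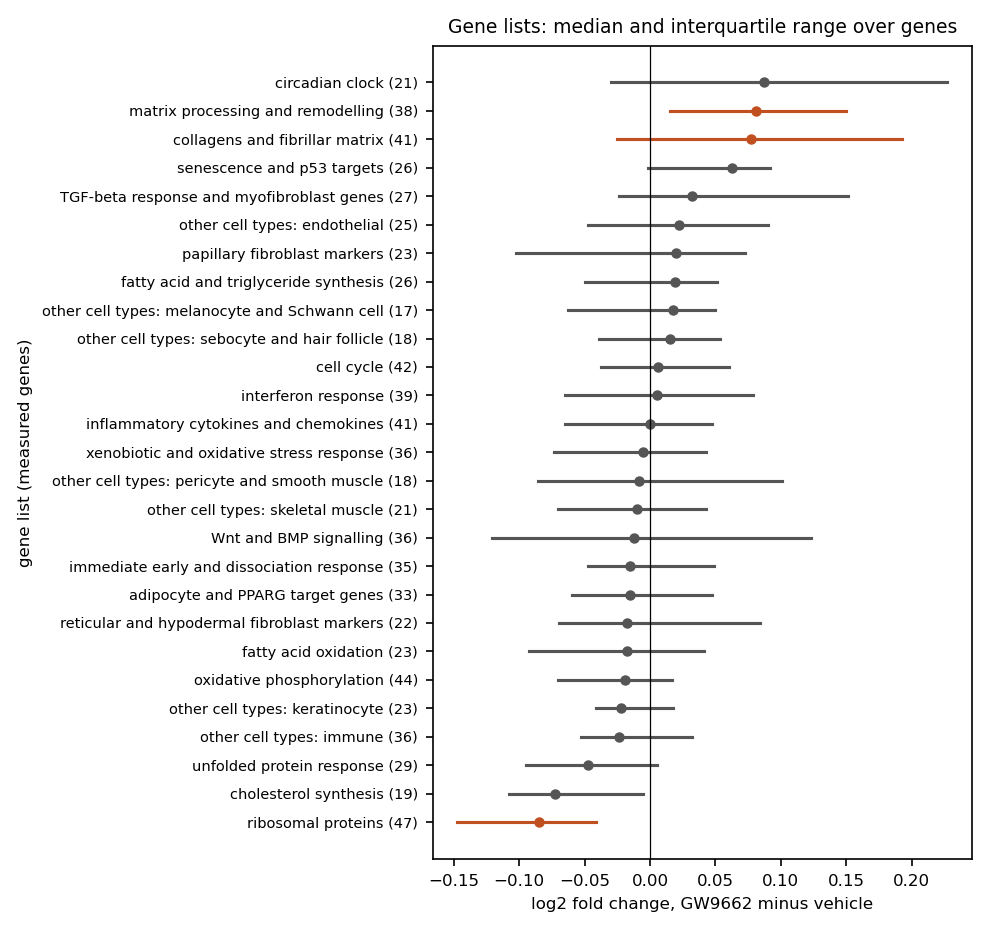
Median (point) and interquartile range (line) of log2 fold changes, GW9662 minus vehicle (x axis), over the measured genes of each of 27 lists (y axis, number measured in parentheses). The 3 lists drawn in orange, ribosomal proteins at -0.09 and both matrix lists at 0.08, had a camera adjusted p under 0.05 with the preset correlation, and adjusted p = 0.981 with an estimated correlation.

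Fibroblast subtype and signalling lists showed no call in the main test. Papillary fibroblast markers had 12 of 23 genes higher (median 0.02, camera adjusted p = 0.960), with Crabp1, a retinoic acid binding protein, at 0.46 ± 0.24 (SE; 0.22 without vehicle 4), Lef1 at 0.12 and Ntn1 at -0.10. Crabp1 passed adjusted over the list alone in the fit with the replicate block and in those without vehicle 4 and GW9662 4, but not in the main test. Reticular and hypodermal fibroblast markers had 13 of 22 measured genes lower (median -0.02, adjusted p = 0.960), with Plpp3 at -0.12, Pi16 at -0.23 and Mgp, matrix Gla protein, at 0.39 (0.16 without GW9662 1). TGF-beta response and myofibroblast genes had 16 of 27 higher (median 0.03, adjusted p = 0.154), with Inhba at 0.43 ± 0.17 (0.18 with the mean of its probe sets, 0.29 without GW9662 1), Itgav at 0.23 ± 0.10 (0.08 likewise) and Tgfb1 at -0.28 ± 0.13. Without vehicle 3 the TGF-beta list was called higher with the preset correlation (adjusted p = 0.0278), and on all 8 samples its adjusted p was 0.981 with an estimated correlation. Wnt and BMP signalling had 19 of 36 lower (median -0.01, adjusted p = 0.960), with Bmpr2, a BMP receptor, at 0.17, Nog, the BMP antagonist noggin, at -0.20 and Dkk2, a Wnt antagonist, at 0.58. At an unadjusted p under 0.05 in limma, there were 2 genes of the TGF-beta list and 3 of the Wnt and BMP list, and 0 of both subtype lists. Over all genes, and adjusted over the list alone in the main test, 0 genes of these 4 lists passed.

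Inflammation, senescence, proliferation and stress lists likewise had no call in the main test. Without vehicle 3, with the preset correlation, the inflammatory (adjusted p = 0.0278), senescence (0.0222) and immediate early (0.0222) lists were called higher. On all 8 samples their adjusted p with an estimated correlation was 0.981, 0.981 and 0.990. The unfolded protein response was called lower, also with the preset correlation, without vehicle 4 (0.00169), without vehicle 4 and GW9662 3 (0.0476), and without vehicle 4 and GW9662 4 (0.00956), where the xenobiotic list was called lower too (0.0418). With an estimated correlation both had an adjusted p of 0.981 on all 8 samples. Inflammatory cytokines and chemokines had 20 of 41 measured genes higher and 20 lower (camera adjusted p = 0.942). Il1r1, the interleukin 1 receptor, was at 0.22 (0.16 without vehicle 1, up to 0.35 with another sample left out). Cxcl2 was at 0.26 (0.14 without GW9662 3) and Nfkb2 at -0.16. Interferon response had 21 of 39 higher (median 0.005, adjusted p = 0.942), with Irf9 at -0.18, Ifih1 at -0.12 and Oasl2 at -0.21 (-0.09 without GW9662 3). Senescence and p53 targets had 19 of 26 higher (median 0.06, adjusted p = 0.456). Its member of smallest p was Hmgb2, a chromatin protein, at -0.28 ± 0.08 (SE, or -0.14 with the mean of its probe sets). Next were Cdkn2a, which encodes the cell cycle inhibitor p16, at -0.21 ± 0.07, and Ei24 at 0.22 ± 0.11 (0.14 without vehicle 4). Cell cycle genes were higher in 25 of 42 (median 0.0063, adjusted p = 0.942), with Mki67, a proliferation marker, at 0.16, Mybl2 at -0.13 and Cenpe at -0.11. The immediate early and dissociation response had 23 of 35 lower (median -0.015, adjusted p = 0.960), with Egr2 at 0.17, Egr3 at -0.08 and Hspa1b at -0.16. Xenobiotic and oxidative stress response had 19 of 36 lower (median -0.005, adjusted p = 0.942), with Gpx4, a lipid peroxide reductase, at -0.16 ± 0.05 (-0.08 with the mean of its probe sets), Sod3, extracellular superoxide dismutase, at -0.43 ± 0.19 (-0.27 without GW9662 1) and Gclc at 0.38 ± 0.23 (0.18 without GW9662 4). The unfolded protein response had 21 of 29 lower (median -0.05, adjusted p = 0.592), with Ddit3 at -0.15, Hyou1 at -0.16 and Manf at -0.11. At an unadjusted p under 0.05 in limma, there were 2 genes of the senescence list, 1 of the cell cycle list and 1 of the xenobiotic list, and 0 in the other 4. In the main test none passed over all genes or adjusted over the list alone.

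No list of markers of other skin cells was called in the main test or with a sample left out. The 7 lists had medians from -0.02 to 0.02. Keratinocyte genes had a camera adjusted p of 0.942 (13 of 23 lower; Krt79 at 0.16, Lgals7 at -0.24). Sebocyte and hair follicle genes had one of 0.960 (10 of 18 higher; Padi3 at -0.20, Krt27 at -0.14, Krt73 at 0.13). Immune genes had one of 0.942 (21 of 36 lower; Cd3e at -0.11, Cd52 at -0.11, C1qc at -0.10). Endothelial genes had an adjusted p of 0.773 (13 of 25 higher; Tek at -0.38, or -0.22 without vehicle 4, Cldn5 at 0.13, Tie1 at 0.12). Melanocyte and Schwann cell genes had one of 0.960 (9 of 17 higher; Foxd3 at -0.11, Mlana at 0.45, or 0.13 without GW9662 1, Mitf at -0.18). Pericyte and smooth muscle genes had one of 0.960 (10 of 18 lower; Kcnj8 at -0.39, or -0.21 without GW9662 3, Higd1b at 0.16, Ndufa4l2 at 0.34, or 0.17 without vehicle 3). Skeletal muscle genes had one of 0.942 (11 of 21 lower; Tnnt3 at -0.21, Tnnc2 at -0.22, Casq1 at -0.20). No gene of these lists passed limma's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 keratinocyte genes, 1 sebocyte and hair follicle gene and 1 skeletal muscle gene. In 7 of the 27 lists, papillary, reticular, inflammatory, immediate early, Wnt and BMP, melanocyte, and pericyte, the median, the mean and the camera test did not share a sign.

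Many of the single-gene values above depended on 1 sample or on the choice of probe set. Of the 107 named genes, 52 moved by over 1.5 times, in either direction, when some sample was left out. Besides those given with such a value, they were Pparg, Pdgfra, Ptprc, Kit, Cd24a, Pecam1, Dgat2, Adipoq, Tm7sf2, Hmgcs1, Msmo1, Echs1, Cpt2, Nfkb2, Irf9, Mybl2, Egr3, Hspa1b, Hyou1, Manf, Ndufb5, Cycs, Rps24, Krt73, Cd3e, Cd52, C1qc, Cldn5, Tie1, Mitf and Casq1. With the mean of a gene's probe sets 27 moved by over 1.5 times, among them Epcam, Gpat4, Adamts12, Mybl2, Cenpe, Hspa1b, Ndufb5, Cycs, Rps10 and Rps24, each nearer 0.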

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

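The tests of vehicle 4, of the estimated correlation, and of the clock score were chosen after the values had been seen, and the bounds for leaving out vehicle 4 were set again 2 times after its values were known; the splits of the samples and the test by kind of probe set were set before their results.

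Of 278 groups of 4 values tested for a sample far from the other 3, 18 had one, where chance gives about 1 in 20, or 13.9. Vehicle 4 was the far sample in 6 of them. It was lowest of its group for Cd34 (10.49, others 10.77 to 10.81), Ccdc159 (4.0, others 4.10 to 4.12), Map3k14 (6.30, others 6.40) and the beta-actin 3' minus 5' difference (-0.94, others -0.69 to -0.65), and highest for Casq1 (4.75) and the skeletal muscle list mean (0.0753). Vehicle 3 was highest for Pdcl (4.54) and Cxcl2 (3.51) and lowest for the immune list (-0.0213). GW9662 1 was highest for the cholesterol synthesis list (0.139) and the melanocyte and Schwann cell list (0.0371). GW9662 2 was lowest for Cd52 (4.20) and highest for the keratinocyte list (0.0433), and GW9662 4 was lowest for Mybl2 (4.51) and the matrix processing list (-0.102). Single values were flagged for Bmpr2 in GW9662 3 (9.06, others 9.14 to 9.15), Gpx4 in vehicle 2 (9.70, others 9.74) and Kcnj8 in vehicle 1 (8.42, others 7.89 to 7.97). For Gpx4, Cd52 (others 4.27) and Map3k14 the other 3 values were equal at 2 decimals, so even a small gap was flagged.

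The first pattern is the call of 3 lists with the preset correlation. Chance could not be excluded for their number: 31 of the 35 splits of the 8 samples into 4 and 4 called at least as many lists (3 for the real split, highest other 12). For ribosomal proteins, 6 of 35 gave a p as small (real 2.13e-10, smallest other 4.44e-18), while among the 8 splits that part all 4 pairs the real p was the smallest (next 7.93e-10), though 8 splits are too few for a share under 0.05. Genes that vary together between animals whatever the treatment may account for the calls, since the smallest adjusted p with an estimated correlation was 0.981. Whether that test would find a shift among correlated genes was not simulated, so its lack of a call does not exclude one. For ribosomal proteins, the 33 members on probe sets without a shared-match suffix were all lower, with a mean of -0.113. Their camera p with the preset correlation was 8.61e-09. The shift was thus not confined to probe sets marked as shared. Whether unmarked probe sets also match pseudogenes was not tested, so that explanation stays open. Without vehicle 4 alone the collagen mean went from 0.12 ± 0.10 to 0.09 and the matrix processing mean from 0.09 ± 0.07 to 0.05 (SE), but this sets its partner GW9662 4, also the lowest of its group in both lists, against the other animals. Without the pair the means were 0.1858 ± 0.0455 for collagens, 0.09965 ± 0.0498 for matrix processing and -0.1255 ± 0.0491 for ribosomal proteins (SE, n = 3 per group), none of them nearer 0 than with all samples. The collagen mean then lay over 2.78 SE from 0, and those of the other 2 lists within that bound. The pair left out was, however, the only 1 with collagens lower in GW9662 (-0.0654, others 0.1383 to 0.2556). Leaving it out had to raise the collagen mean, so that rise alone cannot clear vehicle 4. The pair's difference was also nearer 0 than the mean for matrix processing (0.0753 against 0.09355) and ribosomal proteins (-0.0579 against -0.1086). Read as pairs, each shift was thus larger on average in the pairs without vehicle 4. Without pairs and without vehicle 4 alone, the means were 0.09 ± 0.10, 0.05 ± 0.07 and -0.08 ± 0.06 (SE; collagens, matrix processing, ribosomal proteins). Vehicle 4 as the whole cause therefore stays open for all 3 lists. The choice of bound decided which list stood out. The bound used before was the adjusted p with the preset correlation and without vehicle 4 alone. Under it the ribosomal list stood out instead (1.74e-04), and collagens (0.292) and matrix processing (0.0476) were open. That p takes little account of genes that vary together. An effect of GW9662 stays open for all 3.

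The second pattern is the place of vehicle 4, at 22.2 on the first principal component (28.2% of the variance), where the other 7 samples lay between -10.4 and 5.49. RNA quality or amplification stays open. The beta-actin 3' minus 5' difference of vehicle 4, -0.94, lay below the range of the others (-0.79 to -0.57). That is toward less 3' relative to 5' signal, so it shows no excess of 3' signal. The Gapdh difference, -0.04, lay within the range of the others (-0.06 to 0.05). Cells of another type in the sort stay open too: 1 of the 7 lists of other cell types, skeletal muscle, which the sort for Pdgfra and Cd34 should remove, lay above the other samples by more than their range, which was the bound set, but in a check added after that result only 1 of its 5 brightest genes, Atp2a1, was highest in vehicle 4. Vehicle 4 was also highest, by less than the bound, for the keratinocyte (0.0716, others up to 0.0433) and the sebocyte and hair follicle list (0.0598, others up to 0.0331). The same held for the melanocyte and Schwann cell list (0.0888, others up to 0.0371). It was not highest for the immune, endothelial and pericyte lists. No biological explanation was tested, since the design names none for 1 animal.

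The third pattern is the shift of clock genes in opposite directions, with Dbp and Cry2 higher and Arntl at -0.59 ± 0.37 (SE). A score of 9 output and period genes minus 4 genes of the opposite phase was put together after the values were seen. It was 0.24 ± 0.50 in GW9662 and -0.24 ± 0.26 in vehicle (SD, n = 4 each), with an exact permutation p of 0.143. That test does not use the pairs. The exact permutation test that flips the signs of pair differences was not run for the score, and it cannot reach the threshold with 4 pairs. Chance differences between animals therefore stay open. Without GW9662 4, where Arntl measured 3.93, the Arntl difference was -0.18 and the score difference 0.29 in place of 0.47. A fixed order of collection of both animals of a day cannot be told apart from treatment: the score was higher in GW9662 in 4 of 4 pairs, which either would give, and times of collection were not analysed here.

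For the count of genes at an unadjusted p under 0.05, chance could not be excluded: 26 of the 35 splits gave at least the 578 of the real split (highest other 1685). At an adjusted p under 0.05 the splits tell nothing, since 35 of 35 must give at least the 0 genes of the real split (highest other 1). The split with 1685 genes set vehicle 3, vehicle 4, GW9662 3 and GW9662 4 against the rest, which points to a structure of the samples. The pairs alone do not describe it. The 3 splits that keep all pairs whole gave 637 to 1685 genes, and the 24 that part 2 pairs gave 388 to 1610. Besides the real split, those that part all 4 pairs gave 353 to 820. The medians were 1002, 777 and 700 in this order. They fell as more pairs were parted, so the pairs are a part of it. With the block, 5 of the 8 splits that part all 4 pairs gave at least the real 825 genes at an unadjusted p under 0.05 (others 451 to 1100), and 7 of 8 called at least 3 lists.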

How the results depend on the processing

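In 1 alternative, the block without vehicle 4 and GW9662 4, chosen after seeing the data, 1 gene passed an adjusted p of 0.05, Col14a1 (0.0396). In all others 0 genes did, all 45037 probe sets, a threshold of 0.1 and the replicate block included; 578 had an unadjusted p under 0.05 (825 with the block, 256 of the brighter 8550 genes, 1597 of all probe sets). The PPARG target list stayed uncalled in every alternative, with a shift from -0.029 to 0.0155 when single samples were left out. On all 8 samples the pairing changed no list call; with the replicate block 2 lists were higher and 1 lower, and 1 gene, Crabp1, passed adjusted over its list alone, as Hmgb2 did (1 gene) after renewed quantile normalisation.

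Both matrix lists and ribosomal proteins had an adjusted p of 0.981 with an estimated correlation, 0.994 by fry and 0.972 with an estimated correlation and the block, so 0 lists were higher and 0 lower there. Fry asks another question, whether the genes of a list move on balance to 1 side, and does not compare them with other genes. Among the brighter genes 1 list was higher, as collagens reached 0.155 with fewer genes tested. With array weights 2 lists were lower, oxidative phosphorylation being added. Without both vehicle 4 and GW9662 3, chosen after seeing the data, 0 lists were higher and 4 lower. Collagens then stood at 0.867 (mean 0.0313), matrix processing at 0.0825 (mean 0.0327) and ribosomal proteins at 0.0207 (mean -0.0599). As many samples were left there as in the next fit. Without the pair of vehicle 4 and GW9662 4, also chosen after seeing the data, 2 lists were higher and 4 lower, 7 genes passed adjusted over a list alone, 868 genes had an unadjusted p under 0.05, and collagens stood at 2.72e-06, matrix processing at 5.96e-05 and ribosomal proteins at 3.27e-11. With the block there, 2 lists were higher and 6 lower, immediate early genes turning to lower (0.00338) and cholesterol synthesis being added (0.00634), and 13 genes passed over a list alone. All these list calls used the preset correlation. Leaving out 1 sample gave 1 to 7 higher lists (7 without vehicle 3), 1 to 4 lower lists (4 without vehicle 4), 0 to 6 genes adjusted over a list alone (6 without GW9662 4, all of matrix lists), 367 to 888 genes at an unadjusted p under 0.05 (367 without GW9662 1, 381 without GW9662 3, 888 without GW9662 4), and adjusted p from 1.07e-08 to 0.292 for collagens. Matrix processing (9.42e-07 to 0.0476) and ribosomal proteins (6.86e-16 to 5.43e-04) were called in each of these. Of the 107 named genes, 1 passed in an alternative, 7 changed sign in at least 1, and 52 moved by over 1.5 times when some sample was left out. Where no cause is given, the cause was not tested. Other scalings moved the median of all genes from -0.005 to -0.0037 or 0, and signal over background was not analysed here.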

Other observations

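The genes below were chosen after their values were seen. In the fit with the replicate number as a block, the smallest p-values belonged to Tnmd, Npr1, Crabp1, Ankrd28, Creb3l3 and Nrep. Tnmd, the tendon gene tenomodulin, was at a log2 fold change of 0.61 ± 0.08 (SE with the block), Nrep at 0.58 ± 0.10, Crabp1 at 0.46 ± 0.07, Ankrd28 at 0.44 ± 0.07 and Creb3l3 at 0.44 ± 0.07, each higher in 4 of 4 pairs. Npr1, a receptor of natriuretic peptides, was at -0.45 ± 0.07 and lower in 4 of 4 pairs. Lrrc15, a membrane protein of activated fibroblasts, had the highest log2 fold change of all genes, 0.98 ± 0.49 (SE without the block), and was higher in 4 of 4 pairs, with 7.14 ± 1.04 against 6.16 ± 0.72 (SD, n = 4). Without vehicle 4 alone the log2 fold change was 0.41 for Tnmd, 0.38 for Nrep, 0.22 for Crabp1, 0.36 for Ankrd28, 0.32 for Creb3l3, -0.25 for Npr1 and 0.62 for Lrrc15. With its partner GW9662 4 left out as well, the log2 fold changes were 0.67, 0.65, 0.40, 0.43, 0.46, -0.41 and 1.04 in the same order. These lay close to the values with all samples or further from 0. For all but Lrrc15 that follows largely from the choice, since a small p with the block requires similar differences over the pairs. Their common direction in 4 of 4 pairs and small SEs with the block follow from it too. In limma with the block, the adjusted p of each of these genes was 0.966. In vehicle 4 Lrrc15 measured 5.09, below the range of the other samples (5.88 to 8.36), as did Mmp3, a stromelysin, at 6.18 (others 6.91 to 8.55).

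Vehicle 4 differed by more than 1 on the log2 scale from the mean of the other samples in 36 genes, where the other 7 samples did so in 5 to 17. Klf1 measured 9.13 there (others 7.19 to 8.34), Plac8 6.92 (others 4.97 to 6.50) and Mme 5.82 (others 6.69 to 7.35). GW9662 3 had the lowest mean of the hybridisation control probe sets, 7.42, against 9.15 to 9.91 in the other samples.

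As a hypothesis, treatment may change how far animals differ from one another rather than the mean. The median SD of a gene was 0.0991 in GW9662 and 0.119 in vehicle, and with 3 samples each it was 0.0889 in GW9662 without GW9662 4 and 0.0971 in vehicle without vehicle 4. The splits of the samples did not exclude chance: 4 of the 35 splits gave a ratio of median SDs as far from 1 (absolute log2 ratio 0.264 for the real split, highest other 0.315).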
